A study of Homo sapiens with 6 samples.

How the data were processed

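SETD5 was silenced in Huh7 cells by siRNA transfection, and poly(A)-selected, stranded mRNA libraries were sequenced, per the labels' protocols. The labels give 3 control and 3 SETD5 knockdown libraries, grouped by their genotype label. The siRNA sequences, the treatment of the control cells, the counting method, the scaling and any filter on genes are not given in the sources used here. The submitters' processing notes name STAR 2.5.1 and R 3.3.0, together with the genome builds hg19 and mm10, without saying which step each was used for. No annotation of hg19 was used here, so no coordinates are printed.

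The authors deposited a single table of log2 values, 14200 genes in 6 columns, named as normalized CPM in log2. In each column, 2 to the power of the value minus 1 falls on whole multiples of a fixed step, with 100% of values within 0.01 of a whole number of reads. The deposited log2 values are thus log2(CPM + 1) of whole reads. Recovered reads per library were 17095417, 14404244 and 14038447 in the controls and 15919552, 16364604 and 16609918 after knockdown. The CPM of a column sum to 0.9934 to 1.0043 of the nominal total, so that the scaling was close to the total but not equal to it. A count of 3 reads, the floor for a gene at 0, corresponds to 0.176 to 0.214 CPM, and 20 genes had 0 reads in at least 1 library. The table holds no gene of the mitochondrial genome. Precision from counting covers counting error only. All 6 columns were used.

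Levels were computed as CPM from the deposited values and are given as means ± SD over the 3 libraries of a group. Genes with a mean of at least 1 CPM over the 6 libraries were tested, which left out 1335. The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided), with the group as the only term, on the log2 values as deposited. P-values were adjusted by the Benjamini-Hochberg method over all 12865 tested genes, with a threshold of 0.05, and 95% confidence intervals come from the same fit. A gene changed at least 2-fold also had an absolute log2 fold change of at least 1. Adjusted p-values of genes named in the text are from this test.

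A set of 44 gene lists with 1108 entries was written before the data were examined. Of the entries, 924 matched the table by the same symbol and 32 by an older or current symbol, and 152 did not match. The 40 lists with at least 5 tested members were tested with camera, at the preset correlation of 0.01 and adjusted over the 40 lists, with camera at an estimated correlation and fry beside it. The remaining 4 lists had fewer than 5 tested members. These were the immune, endothelial, and kidney and cervical marker lists, and a list of mitochondrial genome genes of which none was in the table.

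Genes were named by a rule set before the data were examined. It takes SETD5, then the 12 genes with the highest and the 12 with the lowest log2 fold change. These needed an adjusted p under 0.05, no overlap between groups and a mean of at least 5 CPM in the higher group. From each list it takes up to 4 changed members with the largest absolute change and up to 2 further members with the highest level. Of the members the rule takes, the text names a part, and some are not reported here.

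The replicates were compared by a chi-square statistic of the recovered reads over genes. It was 1.26 to 2.17 per gene between libraries of a group and 19.8 to 24.1 between groups, where sampling alone gives a value near 1. Over genes with at least 2000 reads summed over a pair of libraries, the variation beyond sampling was a CV of 0.87 to 2.41% within groups. It was taken from the median deviation, so it describes a typical well-covered gene. No pair of libraries differed by less than sampling noise, and each was counted as a replicate. This comparison cannot tell separate cultures from repeat libraries of a single culture. The first principal component held 78.3% of the variance and separated the groups.

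The scripts were tested on simulated data of the 12865 genes with the libraries' own depths and a CV of 1.96% beyond sampling. Of 50 genes changed at each size, the test recovered 58% at 1.2-fold, 78% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 15 false calls among 12665 unchanged genes. Of 5 shifted lists all were called by camera, and of 10 unshifted lists none. Every gene was given the same CV, taken from the well-covered genes, so the rates hold for that uniform spread and noisier genes were not simulated. The genes were simulated independently of each other, so false list calls from correlation between genes could not show here.

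Words of 7 bases in 3' UTRs were scanned against the fold changes after adjustment for 3' UTR length, base composition and level. One GENCODE 29 transcript per gene was used, and its sequences gave a 3' UTR for 11731 of the tested genes (91.2%). Gene symbols were matched through tables of current and older names. The 16152 words found in at least 50 genes were tested, with 1000 shuffles of genes for the family-wise p. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.

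Alternatives chosen before the data were examined were no filter on levels, a filter at 5 CPM, a pseudocount of 0.1, median centring and quantile normalization. The others were no mean-variance trend, array weights, the replicate number as a block, leaving out each library in turn, and camera with an estimated correlation. A pseudocount of 1 was also planned and is the deposited scale itself. Limma-voom on the recovered reads, TREAT against a 1.2-fold change, and a fit without genes that hold GCACCT in the 3' UTR were added after seeing the data.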

Results

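The series measured gene expression by RNA sequencing in Huh7, an established human hepatocellular carcinoma cell line with many hepatocyte features. SETD5, which encodes a SET-domain protein of chromatin, was silenced by siRNA transfection, and the labels do not state what the control cells received. The labels give 3 control and 3 SETD5 knockdown libraries, and they do not say whether the 3 libraries of a group came from separate cultures. All p-values below therefore measure only the spread between these libraries, which may be technical. The table held 14200 genes, and 14038447 to 17095417 reads per library could be recovered from its values. The 12865 genes with a mean of at least 1 CPM (reads scaled to the size of the library) were tested. Fold changes are on the log2(CPM + 1) scale, which understates the change of genes at low levels, and levels are given in CPM.

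SETD5, the siRNA target, was lower in every knockdown library than in every control library. Its levels were 212, 210 and 202 CPM in controls 1 to 3 and 136, 140 and 138 CPM in knockdown libraries 1 to 3. The group means were 208 ± 5.56 CPM in the control (SD, n = 3) and 138 ± 2.21 CPM after knockdown (SD, n = 3), a fall of the mean to 0.664 times the control. The log2 fold change was -0.59 with a standard error of 0.032, and the limma adjusted p was 1.15e-17. An exact two-sided permutation test of the 3 against 3 values gave p = 0.1, the smallest that this design allows. The plot of SETD5 levels shows the 6 values.

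**Figure D1:**
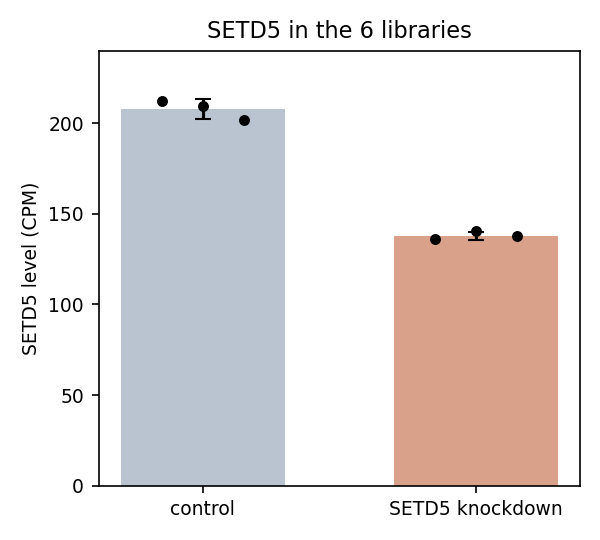
SETD5 level in CPM on the vertical axis for the 3 control and the 3 SETD5 knockdown libraries (points), with the group mean (bar) and SD (error bar). The knockdown libraries lie between 136 and 140 CPM and the controls between 202 and 212 CPM.

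The series asked how the transcriptome of these cells differed after SETD5 depletion. Among genes with a mean of at least 5 CPM in the higher group, the 12 strongest rises included LYPD1, an LY6-family protein, which went from 0.867 ± 0.241 to 8.14 ± 0.613 CPM (SD, n = 3 per group), and the alcohol dehydrogenase ADH1B, from 4.28 ± 0.815 to 24.6 ± 2.35 CPM. CCDC80 rose from 22.2 ± 0.856 to 105 ± 2.85 CPM, and the EGF-receptor ligand AREG from 0.838 ± 0.31 to 7.16 ± 0.0391 CPM. The tubulin TUBB3 rose from 27.3 ± 2.37 to 112 ± 3.17 CPM and TUBA1A from 13.4 ± 1.32 to 50.9 ± 1.64 CPM. The other rises of this group were SPTSSB, TM4SF4, the WNT antagonist SFRP5, STAT4, ADH1A and the microtubule-associated protein MAP1B, at 3.70 to 7.49 times the control. The 3' UTRs of LYPD1 and MAP1B hold GCACCT, that of LYPD1 as a 7-base word. ADH1A and ADH1B, and TUBA1A and other alpha-tubulins, are close paralogs, so the split of reads between them is uncertain.

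Under the same limit on level, the 12 strongest falls included PKM, the pyruvate kinase of most proliferating cells, which went from 1363 ± 38.8 to 466 ± 5.82 CPM, and PKLR, the pyruvate kinase of liver, from 15.1 ± 2.47 to 4.55 ± 0.803 CPM. The angiotensin precursor AGT fell from 692 ± 44.6 to 257 ± 15 CPM and the heparan sulfate proteoglycan SDC4 from 172 ± 2.26 to 51.3 ± 3.24 CPM. The mitochondrial carrier SLC25A43 fell to 0.229 times the control. The activin subunit INHBB, the complement regulators C4BPA and C4BPB, the clotting factor subunit F13B, OSBP2, GBA3 and MYLK3 fell to 0.241 to 0.358 times the control. No 3' UTR of GBA3 could be searched. In the 3' UTRs of SLC25A43, SDC4, OSBP2, PKM and AGT a 7-base or 8-base word around GCACCT was present, which is taken up in the closing section. Below, such words are stated for part of the named genes, so a gene without mention can hold one. Falls named below include SUV39H1, RAD51AP1, HADHA and SDHA with a 7-base word. EDEM1, ETV5, CTGF, DGAT1, DLK1, ME1, FBP1, ITGA2 and COL1A1 hold GCACCT alone. Rises named below include KMT2A, AKR1C1 and ONECUT2 with a 7-base word. TBL1X, DUSP5, GLUL, COL4A6, BMF and NRP2 hold GCACCT alone.

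The limma test called 6706 of the 12865 genes at an adjusted p under 0.05, with 3303 higher and 3403 lower after knockdown. Most changes were small, since the median absolute log2 change of the called genes was 0.27 and 3182 of them changed by less than 1.2-fold. At least 2-fold changes were found for 171 genes, 84 higher and 87 lower. In 7376 genes, 57.3% of those tested, the control and knockdown values did not overlap, where chance gives 10%. Against a change of 1.2-fold, limma's TREAT test called 1466 genes, 640 higher and 826 lower. With a pseudocount of 0.1 in place of 1, 309 genes passed the 2-fold limit, and under voom 327 did. When genes found to hold GCACCT in the 3' UTR were left out, 100 passed it, 60 higher and 40 lower.

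**Figure D2:**
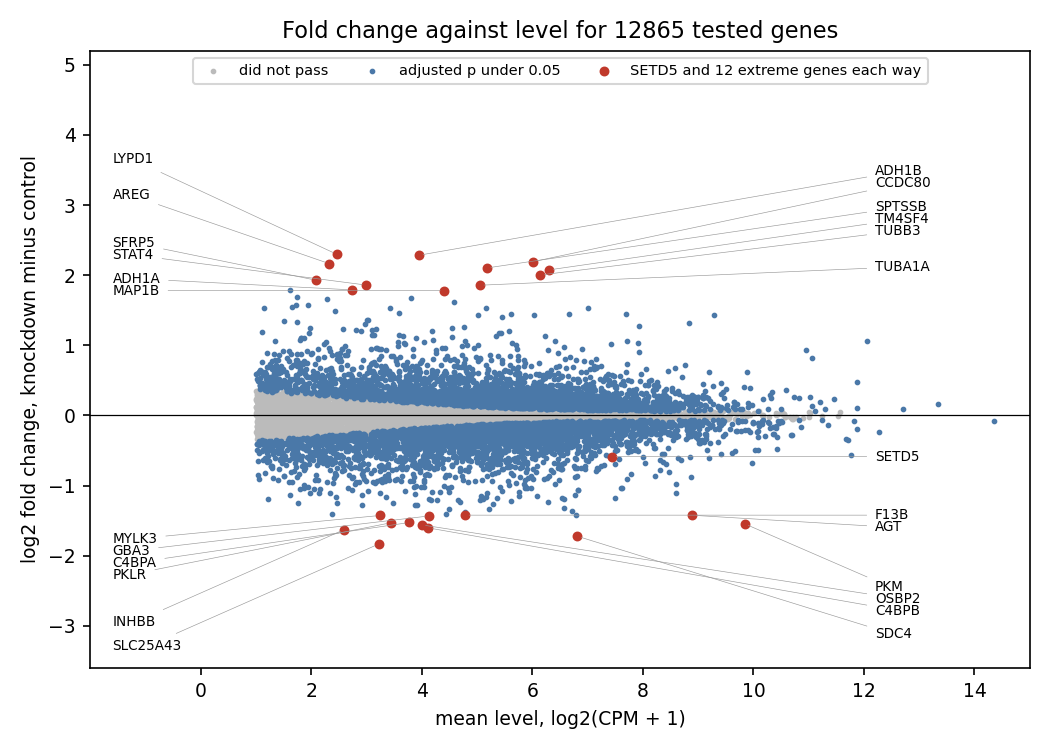
Log2 fold change (knockdown minus control) on the vertical axis against mean level, as log2(CPM + 1), on the horizontal axis for the 12865 tested genes, with genes at limma adjusted p under 0.05 in blue. The named genes in red are SETD5 and the 12 genes with the highest and the 12 with the lowest fold change among those with at least 5 CPM in the higher group, from LYPD1 at 2.30 to SLC25A43 at -1.83.

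Gene lists fixed before the data were examined were compared with all other tested genes by camera, and 14 of 40 lists passed, 4 higher and 10 lower after knockdown. The preset correlation between genes was 0.01. With an estimated correlation none of the 14 calls held (smallest adjusted p = 0.276), although 5 lists had an unadjusted p under 0.05. The estimate was below 0.01 for acute phase proteins (-0.012), drug metabolism (-0.004), fatty acid oxidation (0.002) and WNT targets (-0.031). A higher correlation was thus not why those calls ended. For drug metabolism the unadjusted camera p went from 0.00023 to 0.0159, and for fatty acid oxidation from 2.74e-05 to 0.0107. The camera settings therefore differ in more than the correlation used. A call lost with an estimated correlation is not by itself a sign of correlated genes, and the cause was not tested. The other called lists had estimates of 0.055 (HIF targets) to 0.284 (cytoplasmic ribosomal proteins). By fry, which asks whether a list's genes move on balance one way, 32 lists passed, and all 40 passed for change in either direction. Neither fry test compares a list with other genes. Adjusted over the list alone, the counts of changed members matched those over all genes unless given below.

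Genes of glycolysis fell together: of 23 tested members, 18 fell and 4 rose, and 5 rose when adjusted over the list alone. The list had a median log2 change of -0.35 and a camera adjusted p of 2.71e-07, with an adjusted p = 0.276 with an estimated correlation. PKM and PKLR led the falls, followed by PFKFB4 (0.559 times the control) and the phosphofructokinase PFKL (0.586 times). GAPDH fell from 3640 ± 54.4 to 2892 ± 60.9 CPM and ENO1 from 1521 ± 29.1 to 1223 ± 14 CPM. The 3' UTRs of PKM, PFKL and GAPDH hold GCACCT, and the 15 members without it had a median of -0.35 and a camera adjusted p of 0.000488. HIF targets, genes induced in low oxygen, went the same way, with 10 of 22 members lower and 4 higher, or 11 and 5 adjusted over the list alone. Their camera adjusted p was 0.0235, with an adjusted p = 0.317 with an estimated correlation and an adjusted p = 0.102 without the mean-variance trend. The mitophagy receptor BNIP3 fell from 131 ± 3.84 to 56.7 ± 2.42 CPM, the kinase PDK1 from 48.6 ± 2.57 to 21.3 ± 1.84 CPM and EPO to 0.537 times the control. All 3 hold GCACCT in the 3' UTR, and without genes of that kind the HIF call ended (camera adjusted p = 0.297, median -0.058). That left 13 members, 4 of them lower and 3 higher, so the loss of members cannot be told apart from the loss of sites. The collagen-modifying enzyme PLOD2, with no such word, fell to 0.665 times.

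**Figure D3:**
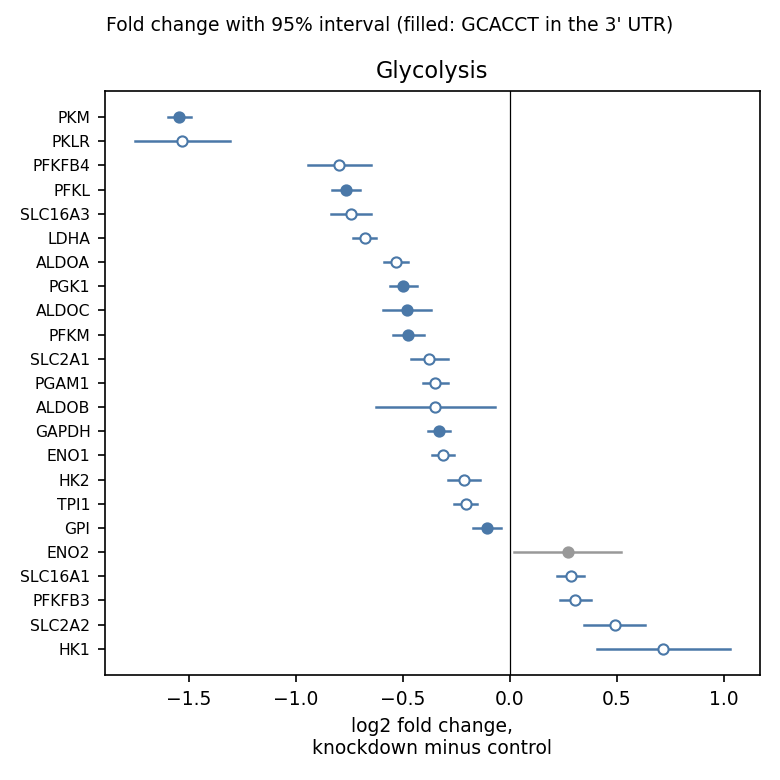
Log2 fold change (knockdown minus control, horizontal axis) with its 95% confidence interval for each of the 23 tested members of the glycolysis list, blue where limma adjusted p was under 0.05 and grey otherwise. Filled circles hold GCACCT in the 3' UTR and open circles do not; 18 members fell, with PKM at -1.55 and PKLR at -1.53.

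Neighbouring pathways of glucose use did not pass camera. Of 9 gluconeogenesis genes, 6 fell and 2 rose (camera adjusted p = 0.135): TAT fell to 0.433 times, the glucose-6-phosphate transporter SLC37A4 to 0.71 times and FBP1 to 0.643 times the control. MDH1 fell to 0.887 times. Pentose phosphate and NRF2 target genes were mixed, with 8 of 19 higher and 7 lower (camera adjusted p = 0.469). The aldo-keto reductase AKR1C1 rose from 336 ± 27.4 to 493 ± 35.6 CPM and the cystine transporter SLC7A11 from 42.9 ± 0.677 to 61.9 ± 5.01 CPM, whereas malic enzyme ME1 fell to 0.671 times and AKR1B10 to 0.648 times the control.

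Genes for proteins that hepatocytes secrete or transport were mostly lower. Of 28 tested members, 23 fell and 3 rose, 24 and 3 adjusted over the list alone, with a median of -0.48. The camera adjusted p was 5.34e-11, with an adjusted p = 0.276 with an estimated correlation. The apolipoprotein APOC3 fell from 34.1 ± 3.38 to 14.2 ± 1.78 CPM, plasminogen PLG from 128 ± 7.03 to 56 ± 3.57 CPM, the asialoglycoprotein receptor ASGR1 to 0.592 times and transthyretin TTR from 420 ± 16.9 to 260 ± 9.97 CPM. Small differences were seen in abundant members: albumin ALB was at 6488 ± 171 and 6912 ± 92.6 CPM, and AFP at 21336 ± 163 and 20268 ± 159 CPM. Neither passed limma without control replicate 1 (adjusted p = 0.0712 for ALB and 0.0625 for AFP), and AFP did not without control replicate 3 (0.0891) or knockdown replicate 1 (0.0654). Both limma calls also ended without the mean-variance trend (adjusted p = 0.0903 for ALB and 0.114 for AFP). Under median centring AFP did not pass limma (adjusted p = 0.0587). Under quantile normalization both log2 changes were 0, but that method gives genes of equal rank the same value in each library. AFP was the highest gene in every library, so its 0 was fixed in advance, and the 0 of ALB can arise the same way. Neither 0 is evidence about the change.

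Acute phase proteins fell in 10 of 15 members and rose in 3, with a camera adjusted p of 0.0348 and an adjusted p = 0.276 with an estimated correlation. The call also ended without knockdown replicate 2 (adjusted p = 0.0502) and without the mean-variance trend (0.098). Hemopexin HPX fell to 0.481 times and complement factor B, CFB, to 0.625 times the control. The fibrinogen chains went the other way, FGG from 1371 ± 17.6 to 2605 ± 83.1 CPM, FGA from 1534 ± 10.3 to 2719 ± 65.9 CPM and FGB to 1.18 times the control. Drug metabolism and bile acid genes fell in 12 of 20 members, 13 adjusted over the list alone, and rose in none. Their camera adjusted p was 0.00131, with an adjusted p = 0.276 with an estimated correlation. UGT2B4 fell to 0.511 times, the bile acid transporter subunits SLC51B and SLC51A to 0.526 and 0.57 times, and the sulfotransferase SULT2A1 from 140 ± 4.32 to 82.5 ± 2.52 CPM. UGT2B4 and GSTA1 (0.723 times) belong to families of near-identical copies and are uncertain for that reason. Hepatocyte transcription factors did not pass camera (11 of 20 higher, 5 lower, adjusted p = 0.061). That p was 0.0333 without control replicate 3 and 0.0495 with no filter on low values. ONECUT1 and ONECUT2 rose to 1.78 times and GATA6 to 1.44 times the control, CEBPA fell to 0.793 times, and HNF4A stood at 350 and 348 CPM without passing.

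Fatty acid oxidation and PPARA target genes fell in 16 of 22 members and rose in 3, with 17 and 3 adjusted over the list alone. The camera adjusted p was 0.000183, with an adjusted p = 0.276 with an estimated correlation. The carnitine carrier SLC25A20 fell to 0.687 times, ACOT2 to 0.684 times and HADHA to 0.802 times the control. Nuclear-encoded oxidative phosphorylation genes fell in 24 of 33 members and rose in none, 25 adjusted over the list alone. The median change was small at -0.11, and the camera adjusted p was 6.37e-05, with an adjusted p = 0.276 with an estimated correlation. ATP5G1 fell to 0.672 times, SDHA to 0.705 times and NDUFB3 to 0.736 times the control, whereas ATP5B was at 1244 and 1230 CPM and did not pass, and turned to a rise of 0.081 under quantile normalization. Fatty acid synthesis and lipid storage genes fell in 14 of 24 members and rose in 4 (camera adjusted p = 0.00949), with an adjusted p = 0.434 with an estimated correlation. The lipid droplet proteins CIDEC and CIDEB fell to 0.359 and 0.592 times, and DGAT1, which makes triglyceride, to 0.655 times the control. The desaturase SCD was at 2976 and 2944 CPM, without passing. Without genes that hold GCACCT in the 3' UTR this call ended (camera adjusted p = 0.135, median -0.13). That left 12 members, 6 of them lower and 2 higher, so the loss of members cannot be told apart from the loss of sites. Cholesterol synthesis genes split, with 7 of 25 higher and 10 lower (camera adjusted p = 0.682): TM7SF2 rose to 1.60 times, and INSIG1 and PMVK fell to 0.768 and 0.751 times the control.

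**Figure D4:**
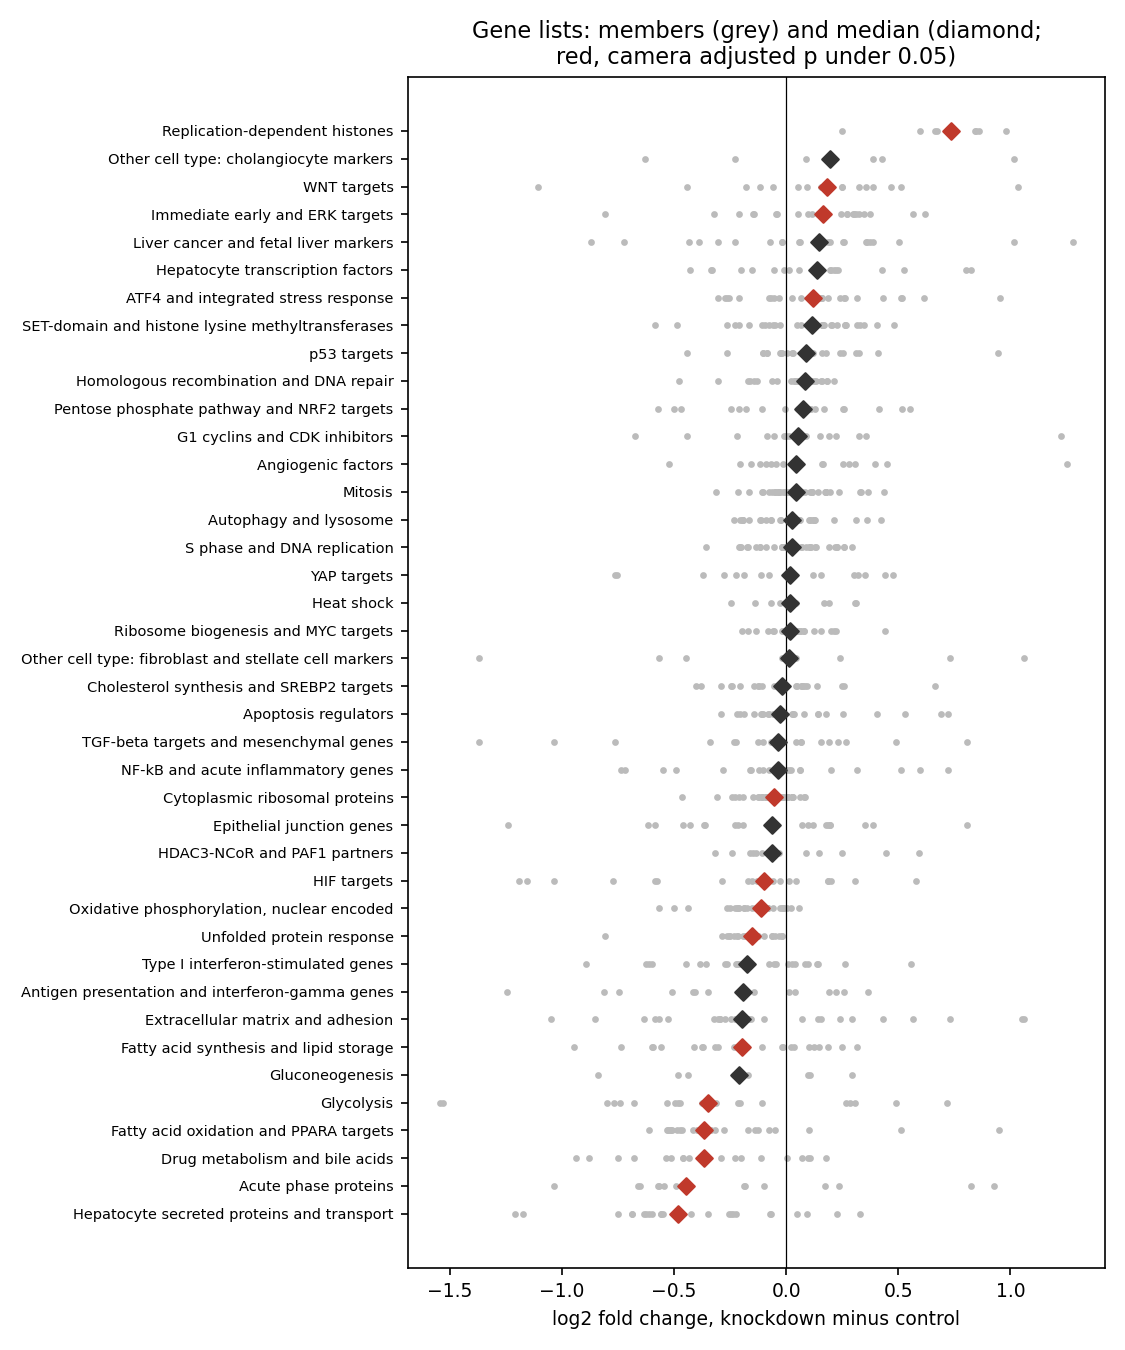
Log2 fold change (knockdown minus control, horizontal axis) of every tested member (grey points) and the median (diamond) of the 40 gene lists with at least 5 tested members, ordered by median. Red diamonds mark the 14 lists with camera adjusted p under 0.05, from hepatocyte secreted proteins at -0.48 to replication-dependent histones at 0.74.

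Genes of the unfolded protein response fell in 17 of 22 members and rose in none, with a camera adjusted p of 4.99e-05 and an adjusted p = 0.276 with an estimated correlation. EDEM1, which targets misfolded glycoproteins for degradation, fell from 73.7 ± 1.62 to 41.7 ± 3.06 CPM, the chaperone HSP90B1 from 1798 ± 61.8 to 1475 ± 41.6 CPM, and HSPA5 to 0.897 times the control. ATF4 and integrated stress response genes rose in 16 of 29 members and fell in 5. Their camera adjusted p was 0.00718, with an adjusted p = 0.371 with an estimated correlation. CHAC1, which degrades glutathione, rose from 8.80 ± 1.1 to 17.9 ± 1.64 CPM, asparagine synthetase ASNS to 1.54 times and the cystathionine synthase CBS to 1.43 times the control. Heat shock genes did not pass camera (4 of 14 higher, 2 lower, adjusted p = 0.461). HSPB1 rose to 1.24 times the control.

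Replication-dependent histone genes rose in 8 of 9 tested members and fell in none, with a median of 0.74. The camera adjusted p was 5.02e-07, with an adjusted p = 0.276 with an estimated correlation. HIST1H2BK rose from 204 ± 5.27 to 323 ± 6.92 CPM, the linker histone HIST1H1C from 108 ± 1.28 to 173 ± 7.49 CPM, HIST1H2BD from 25.8 ± 1.38 to 47.5 ± 2.33 CPM and HIST1H4H from 3.09 ± 0.369 to 7.08 ± 0.604 CPM. The libraries were made from mRNA captured on poly-T beads, while most messages of these genes carry no poly(A) tail, so the values cover the polyadenylated part. Near-identical copies make single members uncertain.

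Among chromatin genes, 15 of 33 SET-domain and histone lysine methyltransferases rose and 5 fell, 15 and 6 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.106). Besides SETD5, SUV39H1, which methylates histone H3 at heterochromatin, fell to 0.709 times, while KMT2A and KMT2E rose to 1.40 and 1.33 times the control. Partners of the HDAC3-NCoR and PAF1 complexes were split, 4 of 14 higher and 6 lower, 5 and 6 adjusted over the list alone (camera adjusted p = 0.901). The demethylase KDM4A rose to 1.52 times and TBL1X to 1.37 times, and LEO1 fell to 0.80 times the control.

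Cell cycle lists did not pass. Mitosis genes rose in 15 of 37 members and fell in 5 (camera adjusted p = 0.105, and 0.0449 without control replicate 2). CENPF rose from 171 ± 6.45 to 232 ± 14.4 CPM, KIF2C to 1.29 times and TOP2A from 616 ± 22.7 to 777 ± 20.2 CPM. S phase genes rose in 13 of 38 members and fell in 8 (adjusted p = 0.46 by camera), with MCM3 at 1.23 times the control. Of 19 G1 cyclins and CDK inhibitors, 5 rose and 3 fell (camera adjusted p = 0.371). The CDK inhibitor CDKN1C rose from 2.56 ± 0.262 to 7.36 ± 0.994 CPM, CDKN2C fell to 0.613 times, and CCND1 was at 265 and 275 CPM without passing. Of 25 p53 targets, 10 rose and 2 fell, 9 and 2 adjusted over the list alone (camera adjusted p = 0.115), with TP53INP1 at 1.93 times and PLK2 at 1.34 times the control. CDKN1A, a CDK inhibitor induced by p53, fell to 0.646 times the control, a limma call that ended without control replicate 2 (adjusted p = 0.0728) and without knockdown replicate 1 (0.0548). Homologous recombination and DNA repair genes rose in 8 of 28 members and fell in 5 (camera adjusted p = 0.451). RAD54L rose to 1.16 times and CHEK1 to 1.14 times, and RAD51AP1 fell to 0.714 times and CHEK2 to 0.806 times the control.

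Of 45 cytoplasmic ribosomal protein genes, 19 fell and 3 rose, with a median of -0.055. The camera adjusted p was 0.00949, with an adjusted p = 0.598 with an estimated correlation, and the call ended without knockdown replicate 1 (adjusted p = 0.055). RPS28 fell from 346 ± 2.69 to 251 ± 4.98 CPM and RPS12 from 1205 ± 39.6 to 972 ± 15.3 CPM. These genes have many processed pseudogenes, which makes their levels uncertain. Ribosome biogenesis and MYC targets rose in 7 of 27 members and fell in 4, 6 and 3 adjusted over the list alone (camera adjusted p = 0.371), with ornithine decarboxylase ODC1 at 1.36 times the control.

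Signalling targets showed a pair of called rises. WNT targets rose in 8 of 17 members and fell in 3. Their camera adjusted p was 0.0348, with an adjusted p = 0.276 with an estimated correlation and an adjusted p = 0.102 without the mean-variance trend. The WNT antagonist DKK1 rose from 156 ± 2.81 to 321 ± 14.7 CPM and glutamine synthetase GLUL from 570 ± 10.3 to 788 ± 18.1 CPM, whereas the ammonium transporter RHBG fell to 0.376 times the control. Immediate early and ERK target genes rose in 14 of 23 members and fell in 5. Their camera adjusted p was 0.0352, with an adjusted p = 0.513 with an estimated correlation. That call ended without control replicate 2 (adjusted p = 0.0781), without knockdown replicate 1 (0.0725) and without knockdown replicate 3 (0.0523), and with a filter at 5 CPM (0.0588) or no mean-variance trend (0.0848). The phosphatases DUSP5 and DUSP4, which switch off ERK, rose to 1.54 and 1.49 times, and the transcription factor ETV5 fell to 0.567 times the control. YAP targets were split, 6 of 19 higher and 7 lower, 7 and 7 adjusted over the list alone (camera adjusted p = 0.701), with CTGF falling to 0.587 times the control.

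Adhesion and matrix genes changed in both directions. TGF-beta targets and mesenchymal genes rose in 7 of 21 members and fell in 7 (camera adjusted p = 0.451). TAGLN fell to 0.383 times the control, at 57.5 ± 3.88 CPM, and ITGA5 to 0.586 times, while N-cadherin CDH2 rose from 103 ± 3.55 to 181 ± 1.41 CPM. Epithelial junction genes rose in 7 of 21 and fell in 10, 8 and 10 adjusted over the list alone (camera adjusted p = 0.469). E-cadherin CDH1 fell from 109 ± 4.04 to 45.5 ± 1.29 CPM, and occludin OCLN rose to 1.79 times the control. The 3' UTRs of TAGLN, ITGA5 and CDH1, as well as that of OCLN, hold GCACCT. Extracellular matrix and adhesion genes rose in 9 of 26 members and fell in 14, with a median of -0.20 (camera adjusted p = 0.178). Of the 14 members without GCACCT in the 3' UTR, 7 rose and 5 fell, and the median turned to 0.11 (camera adjusted p = 0.966). COL1A2 rose from 135 ± 2.41 to 282 ± 6.06 CPM and COL4A6 to 2.18 times, and the integrins ITGA3 and ITGA2 fell to 0.344 and 0.536 times the control. Of 17 angiogenic factors, 6 rose and 4 fell, 7 and 4 adjusted over the list alone (camera adjusted p = 0.335), with NRP2 at 2.48 times the control.

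Immune pathways did not pass camera. Type I interferon-stimulated genes fell in 10 of 27 members and rose in 3 (adjusted p = 0.278 by camera). IFIH1, a sensor of double-stranded RNA, fell from 2.21 ± 0.488 to 0.714 ± 0.0247 CPM and USP18 to 0.627 times the control. Antigen presentation and interferon-gamma genes fell in 7 of 15 and rose in 2 (camera adjusted p = 0.178). GBP1 fell to 0.336 times and TAP2 to 0.548 times the control, and B2M was at 295 and 303 CPM without passing. NF-kB and acute inflammatory genes fell in 6 of 20 and rose in 4 (camera adjusted p = 0.461). ICAM1 and CCL20 fell to 0.591 and 0.604 times, and CXCL6 rose to 1.59 times the control.

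Apoptosis regulators rose in 6 of 25 members and fell in 6 (camera adjusted p = 0.545), with the BH3-only genes BMF and BCL2L11 at 1.63 and 1.45 times the control. Their median was -0.027 and their mean 0.063, so the signs differed. Autophagy and lysosome genes rose in 9 of 30 and fell in 9 (camera adjusted p = 0.703), with ULK1 at 1.29 times the control. Liver cancer and fetal liver markers rose in 13 of 24 and fell in 7 (camera adjusted p = 0.061, and 0.0493 without control replicate 3). Without genes that hold GCACCT in the 3' UTR the list passed camera as higher (adjusted p = 0.00233, median 0.25). With an estimated correlation the whole list had a camera adjusted p of 0.276. SOX4 rose from 140 ± 1.8 to 342 ± 6.67 CPM and SPP1 to 2.16 times, and DLK1 fell to 0.542 times the control.

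Markers of other cell types gave no common direction. Of 4 tested immune markers, LYZ, which Huh7 cells expressed at 260 ± 13.1 CPM in the control, rose to 649 ± 41.1 CPM, and CD14 fell from 3.62 ± 0.169 to 1.76 ± 0.264 CPM. PTPRC, present on nearly all leukocytes, was at 1.13 and 1.59 CPM and did not pass. No endothelial marker was tested, since none of the 2 in the table reached the level filter. Of 8 fibroblast and stellate cell markers, 3 rose and 3 fell (camera adjusted p = 0.864): COL3A1 rose to 1.97 times and COL1A1 fell to 0.659 times the control. Cholangiocyte markers rose in 5 of 7 and fell in 2 (camera adjusted p = 0.188), with GGT1 at 0.635 times the control. Of 3 tested markers of embryonic kidney and cervical lines, CDKN2A fell to 0.856 times the control, and TP63 did not pass. The fibroblast list shares COL1A2 and TAGLN, and the cholangiocyte list SPP1 and SOX9, with other lists.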

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

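The voom fit, TREAT and the fit without GCACCT genes were chosen after the data were seen; the other alternatives were set before the data were examined. SETD5 stayed lower and past the threshold under all 16 alternatives run on it, with log2 changes of -0.57 to -0.61. The number of changed genes was 5868 to 6898 over the alternatives set beforehand, and 5979 to 6331 when a library was left out. Under TREAT it was 1466, with 640 higher and 826 lower, by the construction of that test. Without GCACCT genes 4639 genes were called, 2200 of them lower, from fewer genes tested. The number of genes changed at least 2-fold was 169 to 179 with a library left out. It was 309 with a pseudocount of 0.1 (162 higher, 147 lower), 327 under voom (171 higher, 156 lower) and 100 without GCACCT genes (40 lower). A smaller pseudocount shrinks low genes less; under voom the offset and the weights changed together, and the cause was not tested. With a library left out, 12 to 16 lists passed camera. With an estimated correlation 0 lists passed, with 5 at an unadjusted p under 0.05; fry called 32. Without the trend 10 passed; the HIF, acute phase, ERK and WNT calls ended (adjusted p = 0.102, 0.098, 0.0848 and 0.102) and the cause was not tested. Over 680 list values, 647 kept their call, 26 lost it, 7 gained it and no called direction turned. The medians of lists called in neither fit changed sign 14 times; without GCACCT genes that of extracellular matrix and adhesion went from -0.20 to 0.11 and that of TGF-beta targets from -0.038 to 0.054. Over 4011 values of 257 named genes, 3922 kept their call, 62 lost it, 22 gained it and 5 turned. Under quantile normalization HMGCS1 turned to -0.0175, ATP5B to 0.081, HSPA8 to -0.10, NPM1 to -0.081 and PEG10 to -0.10; the cause was not tested. Libraries with the same number deviated together weakly at most, with correlations of -0.0109 to 0.0541. Those with other numbers gave -0.0596 to 0.0215, so a pairing by number was neither clear nor excluded. The replicate block called 6898 genes, 171 at least 2-fold, and 16 lists, with SETD5 at -0.59; it gained hepatocyte transcription factors and liver cancer markers (adjusted p = 0.0475 for both). Not every library correlated best with its own number. Depth limits the low genes: at 14038447 reads, 3 reads are 0.214 CPM, and the simulated test found 58% of 1.2-fold changes.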

Other observations

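Tests of the splits, of the GCACCT words, of PKM and of the glycolysis members without sites were chosen after the results were seen. Those of transcript length and GC content for glycolysis and ZNF genes, and of ZNF genes without GCACCT, are recorded as written beforehand. The ZNF rise and the word GCACCT were themselves found in these data, so the ZNF tests are not independent of them. Genes were also grouped by the letters before the first digit of their symbol, and 3 of 152 such families passed camera, all higher after knockdown. Zinc finger genes named ZNF rose in 180 of 449 members and fell in 25, with a median log2 change of 0.15 (camera adjusted p = 0.00135, and adjusted p = 0.361 with an estimated correlation). ZNF608 rose from 12.8 to 31.7 CPM, ZNF217 from 60.4 to 87.9 CPM and ZNF84 from 22.3 to 35.8 CPM, and ZNF704 fell from 21.2 to 12.5 CPM. Histone genes named HIST rose in 17 of 24 members and fell in none (camera adjusted p = 8.49e-06, and adjusted p = 0.507 with an estimated correlation), and these overlap the histone list of the report. Collagen genes rose in 11 of 22 and fell in 3 (camera adjusted p = 0.0328, and adjusted p = 0.718 with an estimated correlation). COL14A1 rose from 9.98 to 24.3 CPM and COL9A2 from 33.4 to 60.6 CPM. The 3 family medians stayed above 0 under median centring, quantile normalization and voom. The genes named in this paragraph were chosen after their values were seen.

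Some other genes that rose at least 2-fold were likewise chosen after their values were seen, and no group of them was tested. The pancreatic and duodenal factor PDX1 rose from 16.5 ± 0.662 to 46.1 ± 1.66 CPM, RFX6 from 1.82 ± 0.544 to 6.87 ± 1.14 CPM, the peptide gene NTS from 110 ± 2.64 to 299.6 ± 0.85 CPM and RELN from 339 ± 11.5 to 914 ± 61.3 CPM (SD, n = 3 per group). The mRNA of HIF1A itself fell from 415 ± 0.429 to 325 ± 4.92 CPM.

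The 7-base words of 3' UTRs were scanned. Genes with AGCACCT in the 3' UTR were lower (z = -13.09, family-wise permutation p = 0.001, the smallest that 1000 shuffles can give), and GCACCTA followed at z = -11.47. The most extreme word in any shuffle reached 5.26, and no word went up by more than z = 4.14. Words unlike these, AATTAGC (z = -6.53) and GGATCAC (z = -5.53), also went past that limit and were not followed up. Of the genes that fell at least 2-fold, 45.8% of 83 searched held a 7-base or 8-base site, against 9.5% of 84 that rose and 14.3% of all searched. Length, base composition and level of the 3' UTRs do not account for it, since after adjustment 199 genes with the 8-base word AGCACCTA still lay -0.249 below genes without a site (95% interval -0.303 to -0.195, genes taken as independent). A candidate explanation is seed pairing of a transfected siRNA. The coding part of the SETD5 transcript holds AGCACCTA at positions 2852 to 2859, as do 6.8% of transcripts of like length. That word was chosen from these same data, and the share of transcripts with the shorter AGCACCT, the leading word, was not computed. The siRNA sequence and the treatment of the controls are not given, and only 1 knockdown condition was made. A consequence of SETD5 loss thus stays open and untested.

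GCACCT in the searched 3' UTRs did not account for the whole fall of the glycolysis list, because the members without it there had a median of -0.348. Only 1 transcript per gene was searched, and sites before the 3' UTR were not counted for these members. Sites of those kinds thus stay open. Adjustment for transcript length, GC content and level left the list at -0.345 below other genes (95% interval -0.566 to -0.124, permutation p = 2e-05, genes taken as independent), whereas with an estimated correlation the list did not pass camera (adjusted p = 0.276). For PKM alone the matter cannot be told apart, since its 3' UTR holds 2 copies of GCACCT and 1 of AGCACCT. A further 1 copy of AGCACCT lies before its 3' UTR. Of 643 genes with at least as many in the 3' UTR, 0.62% (4 genes, PKM itself among them) fell as far, and the median of the 643 was -0.059. Copies before the 3' UTR were not counted in choosing these genes, so they do not match the full set of sites in PKM. A biological effect of SETD5 depletion, the design's contrast, remains open and may act with a site in PKM.

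The rise of the ZNF genes was tested against the same properties. After adjustment for transcript length, GC content and level the family lay 0.147 above other genes (95% interval 0.125 to 0.169). Among genes without GCACCT in the searched 3' UTR, 306 ZNF genes lay 0.152 above the rest (95% interval 0.127 to 0.178). Both values argue against these explanations as the whole cause. The intervals take genes as independent, and reads shared between paralogous zinc finger genes were not tested. A link to SETD5 loss is a hypothesis and was not tested.

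Splits of the 6 libraries into groups of 3 number 10, too few for a share under 0.05. The real split called 6706 genes, 171 of them at least 2-fold, and 14 lists, and in each of these 3 results 1 of the 10 splits, the real one, was as large. The highest among the other splits was 0 genes (158 at an unadjusted p under 0.05), 0 genes at least 2-fold and 10 lists. Each of these other splits mixed control and knockdown libraries in both groups. The difference between control and knockdown then adds to the spread within groups. Few called genes there cannot show what chance alone would call. The number of lists called in the other splits was 1 to 10.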
